A study of Pseudomonas aeruginosa with 10 samples.

How the data were processed

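RNA sequencing of 10 samples of *Pseudomonas aeruginosa* ATCC 9027 was analysed, 5 grown with the peptide DDDY and 5 with sterile water. Per the labels' protocols, precultures of 8 h went into 200 mL of medium with 200 µL of water or with DDDY from a 50 mg/mL solution, and cells were collected after 24 h at 37 °C and 150 rpm. Their wording leaves open how much DDDY solution was added, and no final concentration is stated. RNA was extracted with Trizol and libraries were made from total RNA with a TruSeq RNA kit, per the labels. The authors deposited whole-number read counts per gene, 1 row for each of 5572 genes and 1 column per library, with no normalization. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.2, and the build they name is mm8, a mouse build that does not match the bacterial genes of the table. The counting tool, its handling of strand and of reads shared between similar genes, and the reference sequence are not given in the sources used here, so values of near-identical gene copies such as *tufA* and *tufB*, of overlapping genes and of antisense pairs are uncertain.

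All 5572 row names matched locus tags of a RefSeq gene table of assembly ASM676v1 (strain PAO1), which was used only for gene names and neighbours, and 1753 of them have a symbol other than the locus tag. No coordinates are given, since the build of the counts is not settled. Every count in the table is even, so an alternative with halved counts was run. Groups and replicate numbers came from the sample titles. No label says that the cultures of a group were started separately, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of the same group agreed within sampling noise, with a chi-square over its degrees of freedom of 14.8 to 80.3, so all 10 were counted as separate samples.

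Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16's filterByExpr by group, with a minimum count of 10, which left 3628 genes that hold 99.96% of the counts, 1419 of them with a symbol. Library sizes were scaled by TMM factors, and CPM are edgeR's TMM-scaled counts per 1000000. DDDY was compared with control in a design with group alone by edgeR's quasi-likelihood test with robust estimation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and the common biological coefficient of variation was 23.7%. Standard errors are the log2 fold change over the square root of the quasi-likelihood F, and confidence intervals are at 95%. Log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, and an adjusted p that DESeq2 left out stayed out, which was so for 423 genes.

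There were 45 gene lists, matched by symbol. Of 1513 listed names, 1042 matched a gene of the table and 855 were tested, and the others count as not measured. Lists with at least 5 tested members were tested with camera on log2 CPM at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry asks whether a set's genes move on balance in 1 direction, its mixed test whether they change in either direction, and neither compares a set with other genes. A list's score is the mean log2 CPM of its members in a library. Scores, totals, shares and principal component scores were compared by exact two-sided permutation tests over all 252 relabellings.

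The contents of the lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. Which 12 lists are described 1 by 1, and have their values under the alternatives tabulated, was decided after the values were seen. The rule named the 10 genes with the largest change in each direction among those with a symbol, an adjusted p below 0.05, a mean log2 CPM of at least 3 and no overlap between groups, which gave 0 genes. It further named up to 4 members with the smallest p of each list described, and all members of the tyrosine and phenylalanine list. Genes outside it were chosen after their values were seen: those with the smallest p, the DESeq2 calls with a symbol, members that passed adjusted over the list alone, genes called under an alternative, the neighbours of *hpcB*, the most abundant genes, the chaperone genes of DDDY 5 and the unread genes.

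The alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, no filter, a stricter filter of at least 10 counts in every library of a group, no robust estimation, other thresholds, the replicate number as a block, and leaving out each library in turn. Halved counts, an adjusted p below 0.10, leaving out control 5 and DDDY 5 together, fry's mixed test without standardization, camera with an estimated correlation and 1 library left out, and all changes to the DESeq2 fit other than the fit itself were added after the data were seen. The scripts were tested on simulated counts for the 3628 genes in 10 data sets with 200 changed genes each, and a further 30 genes shifted by 0.5 on the log2 scale for the set test. Of the calls made there outside those 30 genes, 4.28% were false with edgeR and 8.63% with DESeq2.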

Results

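Messenger RNA was measured by RNA sequencing in 10 samples of *Pseudomonas aeruginosa* ATCC 9027, a strain of a Gram-negative bacterium. For 5 samples the liquid medium received DDDY, the peptide Asp-Asp-Asp-Tyr, from a 50 mg/mL solution, and for 5 control samples it received sterile water. All were then grown at 37 °C for 24 h with shaking, and the series' title gives the purpose as the antibacterial mechanism of the peptide. Total counts per library ranged from 5445564 to 10320302 over 5572 genes, which are named by the locus tags of strain PAO1. Every count was even, and if each sequenced pair counted as 2, the libraries held 2722782 to 5160151 pairs. The transcripts of *oprF*, a major outer membrane porin and 1 of the 10 most abundant genes, averaged 25990 ± 3890 counts per 1000000 scaled counts (CPM; SD, n = 5) in control and 28460 ± 3350 CPM (SD, n = 5) in DDDY cultures.

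The comparison of DDDY with control cultures asked which transcripts differed after growth with the peptide. The smallest p-values belonged to genes with lower values in DDDY cultures. PA1009 averaged 141 ± 23.5 CPM in DDDY and 260 ± 53.2 CPM in control cultures (SD, n = 5 each), and *glpR*, which encodes the repressor of the glycerol-3-phosphate regulon, averaged 45.8 ± 11.1 and 92.6 ± 17.3 CPM. Their log2 fold changes were -0.88 ± 0.16 and -1.02 ± 0.18 (SE), and the 5 DDDY libraries lay below all 5 control libraries for both. Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where both had an adjusted p of 0.0643. *hpaA*, which encodes the large component of 4-hydroxyphenylacetate 3-monooxygenase, had a log2 fold change of -0.93 ± 0.20 (SE), at 115 ± 23.8 CPM in DDDY and 220 ± 63.1 CPM in control cultures (SD, n = 5 each). PA4122 and PA1328 had log2 fold changes of -1.10 ± 0.23 and -1.08 ± 0.23 (SE). In the other direction, PA2552 averaged 562 ± 96.2 CPM in DDDY and 336 ± 67.2 CPM in control cultures (SD, n = 5 each), a log2 fold change of 0.74 ± 0.16 (SE). PA0328 and PA2870 had log2 fold changes of 1.31 ± 0.31 and 1.13 ± 0.27 (SE) at fewer than 10 CPM in both groups. *ldh*, the leucine dehydrogenase gene, had 0.72 ± 0.18, and *nirF*, needed for heme d1 synthesis, had 0.56 ± 0.14 (SE). The edgeR adjusted p was 0.134 to 0.158 for these last 8 genes, and all genes of this paragraph were chosen after their values were seen.

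**Figure D1:**
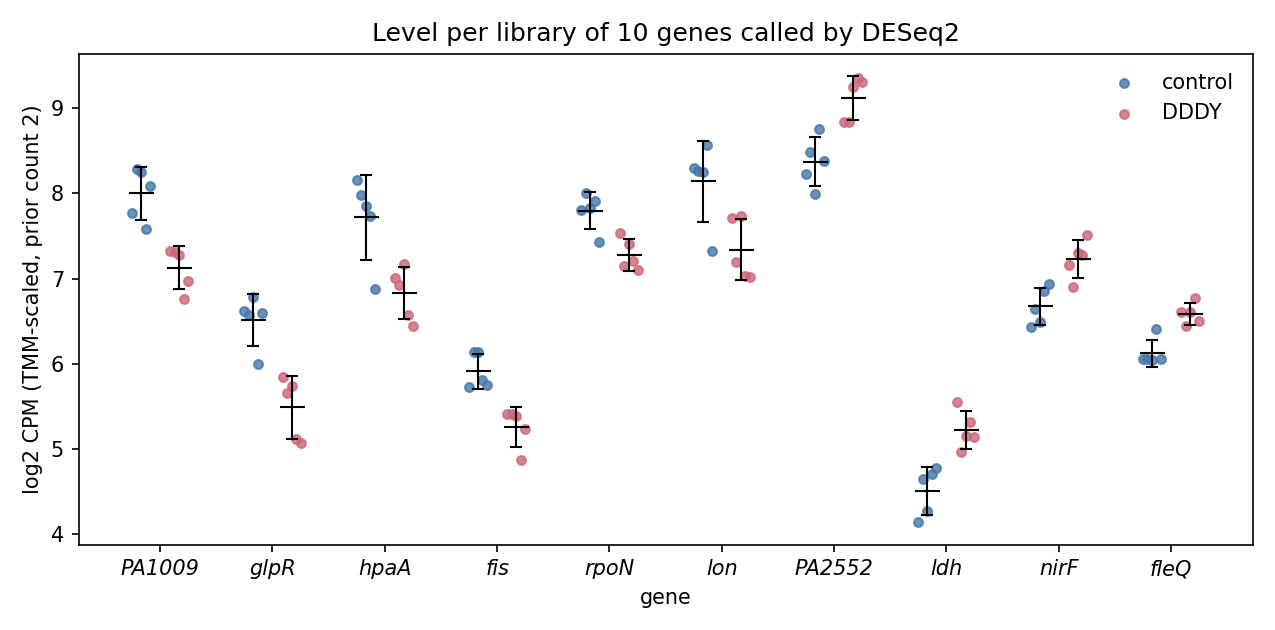
Level of 10 genes in each library as log2 CPM (vertical axis, TMM-scaled) for 5 control (blue) and 5 DDDY (red) libraries, with bars at the mean ± SD. All 10 genes were called by DESeq2 and none by edgeR's quasi-likelihood test. The groups do not overlap for PA1009, *glpR*, *fis*, PA2552, *ldh* and *fleQ*, while control 5 is the lowest control library for *lon*.

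By edgeR's quasi-likelihood test, 0 of 3628 genes had an adjusted p below 0.05 in either direction. At an unadjusted p below 0.05 there were 453 genes, 193 higher and 260 lower in DDDY cultures, where 181 are expected by chance. That split depended on the scaling, with 357 higher and 160 lower under upper-quartile factors and 233 higher and 186 lower under library totals alone. limma-voom called 0 genes and DESeq2 called 71, of which 23 were higher and 48 lower in DDDY cultures. Among the 20 DESeq2 calls with a gene symbol, *fis*, which encodes a nucleoid protein, had a DESeq2 log2 fold change of -0.65 ± 0.16 (SE) and a DESeq2 adjusted p of 0.0116. *rpoN*, the gene of sigma factor 54, had -0.52 ± 0.14, *oprD*, a porin gene for basic amino acids and carbapenems, -0.74 ± 0.22, and *exaB*, the cytochrome c550 gene, -1.19 ± 0.33 (DESeq2, SE). The lower DESeq2 calls also held *glpR*, *hpaA*, *lon*, *pilZ*, *fdxA*, *opdO*, *comL*, *ilvH*, *ureD*, *rnk* and *aguB*, and the higher ones with a symbol were *nirF*, *fleQ*, *tmk*, *gapA* and *ldh*. Leaving out any 1 library moved the DESeq2 count by more than 1.5 times. It was 143 without control 5, 127 without control 4, 119 without DDDY 1, 45 without DDDY 2, 40 without control 1, 32 without DDDY 5, 27 without DDDY 3, 6 without control 3, 5 without control 2 and 3 without DDDY 4, and PA1009 and *glpR* were called each time. The edgeR count was 21 without control 5, 10 without control 4 and 3 without DDDY 1, and it stayed at 0 without any other single library. With the replicate number as a block, edgeR called 3 genes, PA1009, *glpR* and *hpaA*, all lower. The groups did not overlap for 94 genes, 49 higher and 45 lower, where chance gives 0.794% of genes, or 28.8. Both this number and the 181 above are expectations without a spread. Of 100 divisions of the libraries into 5 and 5, the real one included, 5 gave at least 453 genes. The 94 genes were not compared with such divisions, so chance is not excluded for them. The 95% confidence interval of the fold change lay within 2-fold for 2810 genes (77.5%) and within 1.5-fold for 1509 (41.6%). In simulated counts of the same size, edgeR found 34% of genes changed by 1.5-fold, 71.4% of those changed by 2-fold and 90.6% of those changed by 3-fold. Each simulated data set held 200 changed genes and 30 further shifted genes, and each gene was drawn independently of the others. Where fewer genes change, the adjustment is stricter, so a lone change of such a size may be found less often in the real libraries.

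The catabolism of tyrosine, the aromatic residue of the peptide, was covered by a list for tyrosine and phenylalanine catabolism with 14 measured genes. None passed the test, with 9 lower and 5 higher in DDDY cultures. The median log2 fold change was -0.17, which was -0.295 without control 5 and -0.0903 under upper-quartile factors. The list also holds *dhcA* and *dhcB*, both higher, which act on carnitine derivatives. Its counts and median therefore do not describe this pathway alone. *phhA*, which encodes phenylalanine hydroxylase, averaged 3070 ± 356 CPM in DDDY and 3517 ± 685 CPM in control cultures (SD, n = 5 each). The homogentisate pathway genes had log2 fold changes of -0.15 ± 0.17 for *hpd*, -0.26 ± 0.17 for *hmgA*, 0.20 ± 0.14 for *maiA* and 0.05 ± 0.14 for *fahA* (SE). The value for *fahA* turned to -0.0415 without control 5 and to -0.0116 without DDDY 3. The homoprotocatechuate genes *hpcC*, *hpcG*, *hpcD* and *hpcB* had values of -0.69 ± 0.25, -0.58 ± 0.22, -0.44 ± 0.20 and -0.34 ± 0.17 (SE). *dhcB* and *dhcA* had 0.43 ± 0.19 and 0.31 ± 0.20 (SE). The tetrahydrobiopterin recycling gene *phhB*, the aminotransferase gene *phhC* and the regulator gene *phhR* had -0.30 ± 0.15, -0.15 ± 0.11 and 0.26 ± 0.15 (SE). In control 5, the mean log2 CPM of this list was 7.48, below the 7.90 to 8.05 of the other control libraries.

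The list for uptake and breakdown of aspartate, the other residue of the peptide, held 9 tested genes. Of these, 5 were higher and 4 lower, with a median log2 fold change of 0.02. The list also holds the glutamate metabolism genes *gdhA*, *gdhB*, *gltB* and *gltD*, so its counts and median do not describe aspartate genes alone. The aspartate ammonia-lyase gene *aspA* averaged 1825 ± 173 CPM in DDDY and 2126 ± 410 CPM in control cultures, and the asparaginase gene *ansB* averaged 396 ± 104 and 323 ± 46.7 CPM (SD, n = 5 each). The glutamate and aspartate transporter gene *gltP* had a log2 fold change of -0.27 ± 0.14 and the asparaginase gene *ansA* 0.27 ± 0.20 (SE). Of 28 listed names of peptide uptake and peptidase genes, 7 matched and 6 were tested. Of the 6, 3 were higher and 3 lower, with a median of 0.02. Only the porin gene *opdP* among them serves uptake, so these values say little about peptide uptake. Under upper-quartile factors the medians were 0.104 for the aspartate list and 0.109 for the peptide list, and under library totals alone 0.061 and 0.0666. The peptide genes included the aminopeptidase genes *pepN* (0.05 ± 0.12) and *pepP* (0.12 ± 0.10), the dipeptide porin gene *opdP* (-0.22 ± 0.22) and the murein tripeptide ligase gene *mpl* (0.17 ± 0.12; log2 fold change ± SE). Neither list had a member passing the edgeR test, over all genes or adjusted over the list alone. The median turned negative for the aspartate list under limma-voom (-0.00245), under the replicate block (-0.0015) and without control 2 (-0.0362), control 3 (-0.00359), control 5 (-0.00714), DDDY 2 (-0.03) or DDDY 3 (-0.00458). It did so for the peptide list without DDDY 1 (-0.00379). Camera put the aspartate list in the downward direction, against its median.

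Denitrification genes, which allow respiration of nitrate in place of oxygen, were higher in DDDY cultures in 23 of 30 cases, with a median log2 fold change of 0.11, which was 0.0582 without control 1, 0.0597 without DDDY 3 and 0.189 without control 5. *norB*, a nitric oxide reductase subunit gene, averaged 34.7 ± 4.71 CPM in DDDY and 25.9 ± 2.87 CPM in control cultures (SD, n = 5 each), and *narJ*, a nitrate reductase assembly gene, 29.1 ± 5.67 and 22.1 ± 2.61 CPM. *norC*, the partner of *norB*, went the other way with a log2 fold change of -0.65 ± 0.27 (SE). *nirF* passed when adjusted over the list alone (adjusted p = 0.0305 by edgeR) and not over all genes. Camera gave this list the smallest p of the 43 lists tested, 0.01, which adjusted to 0.431, and the p was 0.183 with an estimated correlation. Flagellum and chemotaxis genes were higher in 27 of 41 cases, with a median of 0.08, which was 0.0383 without control 1, 0.0464 without control 3, 0.0417 without DDDY 4 and 0.172 without control 4. *fleQ*, the master regulator of flagellar genes, averaged 96.1 ± 8.61 CPM in DDDY and 70.0 ± 8.29 CPM in control cultures (SD, n = 5 each). *flhF*, which places the flagellum at the pole, had a log2 fold change of 0.48 ± 0.17, the chemoreceptor gene *pctB* -0.45 ± 0.17 and the hook-cap gene *flgD* -0.38 ± 0.20 (SE). Of the flagellar genes, 0 passed the edgeR test over all genes and 0 adjusted over the list alone.

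Amino acid biosynthesis genes were lower in DDDY cultures in 43 of 65 cases, with a median log2 fold change of -0.08 that became 0.00251 under upper-quartile factors and -0.049 without control 5. The acetolactate synthase genes *ilvH* and *ilvI*, for the first shared step of valine and isoleucine synthesis, had values of -0.55 ± 0.14 and -0.36 ± 0.12 (SE). The anthranilate synthase gene *trpE* had -0.36 ± 0.12 and the shikimate kinase gene *aroK* 0.46 ± 0.15 (SE). The mean log2 CPM of the list was 6.71 ± 0.03 in DDDY and 6.77 ± 0.02 in control cultures (SD, n = 5 each; exact permutation p = 0.00794, the smallest that 252 relabellings can give), which adjusted to 0.349 over 44 lists. With so few relabellings, a single list could not pass after that adjustment whatever its values, so the adjusted p decides nothing for this list. Assimilatory nitrogen genes were lower in 9 of 15 cases, with a median of -0.12 that became 0.00245 without DDDY 5, -0.0545 without control 3, -0.0449 without control 4 or DDDY 3 and -0.068 without DDDY 4. They included the urease accessory gene *ureD* (-0.61 ± 0.16), the nitrogen regulatory protein gene *glnK* (-0.67 ± 0.24), the sensor kinase gene *cbrA* (-0.37 ± 0.14) and the sensor kinase gene *ntrB* (0.45 ± 0.19; log2 fold change ± SE). Only *ureD* passed when adjusted over the list alone (adjusted p = 0.0174 by edgeR). This was also the 1 list to pass fry's mixed test, which asks whether a set's genes change in either direction (adjusted p = 1.16e-05), and it no longer passed when genes were not standardized by their variance, where the smallest adjusted p of fry's mixed test over the lists was 0.275.

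Heat shock and protease genes were lower in DDDY cultures in 16 of 23 cases, with a median log2 fold change of -0.12. The median was -0.0548 without DDDY 5, -0.06 without control 4, -0.214 without DDDY 1, -0.219 without DDDY 3 and -0.252 without control 5, and it was -0.0411 under upper-quartile factors, -0.195 with limma-voom and -0.19 with the replicate block. *lon*, which encodes an ATP-dependent protease, averaged 166 ± 41.8 CPM in DDDY and 293 ± 80.7 CPM in control cultures (SD, n = 5 each) and passed when adjusted over the list alone (adjusted p = 0.0194 by edgeR). The chaperonin gene *groEL* had a log2 fold change of -0.41 ± 0.23, the protease subunit gene *hslV* -0.65 ± 0.31 and the cold shock protein gene *capB* 0.46 ± 0.19 (SE). A single library, DDDY 5, held the lowest *groEL* and *dnaK* values. Its *hslV* value was 99 CPM against a mean of 434 ± 108 CPM in the other DDDY libraries (SD, n = 4), and its *dnaK* value was 3522 CPM against 13060 ± 2640 CPM. Envelope stress genes, 13 of 23 higher, had a median of 0.06, which was 0.00325 without DDDY 3, 0.00338 without DDDY 5, 0.00502 without control 1 and 0.0261 without control 2, and 0.144 under upper-quartile factors and 0.103 under library totals alone. Among them the anti-sigma factor genes *mucB* and *mucA* had log2 fold changes of 0.40 ± 0.14 and 0.27 ± 0.14, *tolA* had 0.36 ± 0.19 and the regulator gene *amrZ* -0.47 ± 0.17 (SE).

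Of 11 tested genes linked to cationic peptide resistance, 6 were higher and 5 lower, with a median log2 fold change of 0.05. *speD*, which encodes S-adenosylmethionine decarboxylase of spermidine synthesis, averaged 131 ± 60.4 CPM in DDDY and 315 ± 148 CPM in control cultures (SD, n = 5 each) and passed when adjusted over the list alone (adjusted p = 0.0159 by edgeR). The magnesium transporter gene *mgtA* had a log2 fold change of 2.34 ± 1.12 (SE) that rested on DDDY 5, at 340 CPM, and became -0.11 without that library. With all libraries kept, it was 0.73 with limma-voom and 0.646 with the replicate block. The magnesium transporter gene *mgtE* and the lipid A hydroxylase gene *lpxO1* had -0.19 ± 0.11 and -0.55 ± 0.40 (SE). The list's median became -0.0141 without control 4, -0.00764 without DDDY 2 and -0.109 without DDDY 5, and camera put it downward, against its median. Peptidoglycan and division genes were 19 higher and 20 lower, with a median of -0.02 that became 0.0633 under upper-quartile factors and 0.0157 under library totals alone. It was also positive without control 3 (0.00996), control 4 (0.0536), control 5 (0.0194), DDDY 1 (0.0259) or DDDY 4 (0.012), and the list's mean was 0.00202 and camera's direction upward. Here *minC* and *pbpA* had log2 fold changes of -0.56 ± 0.20 and -0.31 ± 0.12, and *murE* and *murG* 0.42 ± 0.18 and 0.27 ± 0.14 (SE). Ribosomal protein genes were 31 higher and 22 lower, with a median of 0.05. *rpsG*, *rpsT*, *rpsP* and *rplT* had log2 fold changes of -0.51 ± 0.18, -0.45 ± 0.17, 0.33 ± 0.15 and 0.36 ± 0.16 (SE). Without control 5 the ribosomal list passed camera's test (adjusted p = 0.00818, median 0.197) at the preset correlation but not with an estimated correlation of 0.71 (adjusted p = 0.951 by camera). The median was -0.0352 without control 4, -0.0264 without DDDY 2 and -0.0135 without DDDY 5.

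**Figure D2:**
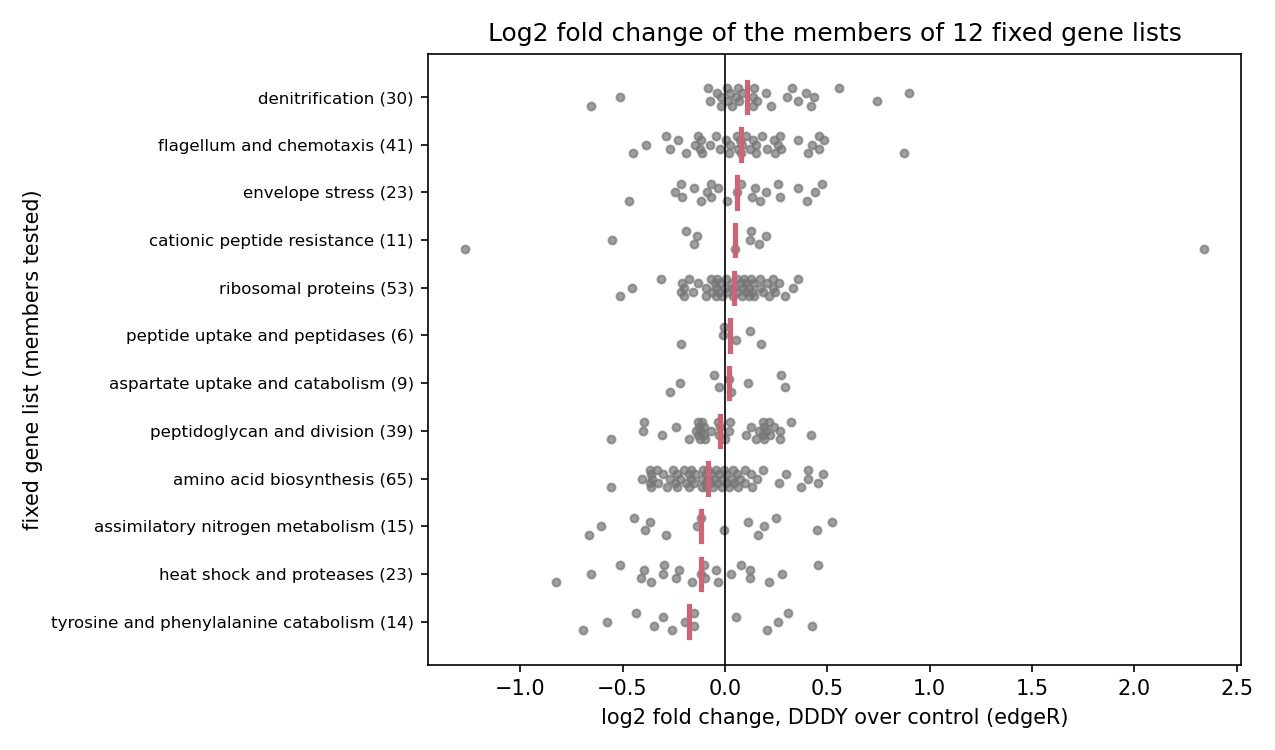
Log2 fold change of DDDY over control (horizontal axis, edgeR) for each tested member (grey points) of 12 fixed gene lists (vertical axis, with the number of members), with the list median as a red bar. The medians lie between -0.17 for tyrosine and phenylalanine catabolism and 0.11 for denitrification, and the point at 2.34 is *mgtA*. Under upper-quartile factors the medians of amino acid biosynthesis and of peptidoglycan and division turn positive.

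Over all 45 fixed lists, 43 had enough members for a set test, and their median log2 fold changes lay between -0.329 and 0.253. Camera passed 0 of them after adjustment and 1 at an unadjusted p below 0.05, and 0 passed with an estimated correlation. Fry's test for movement in 1 direction also passed 0 lists, with 1 at an unadjusted p below 0.05, amino acid biosynthesis. Single members passed in 5 lists when adjusted over the list alone, which were *nirF*, *ureD*, *speD*, *lon* and the pyocin S5 gene *pyoS5* (adjusted p = 0.0342 by edgeR, over 3 members). That adjustment does not cover the number of lists, so some such passes are expected by chance. Over all genes, these 5 had an adjusted p of 0.153 to 0.26 by edgeR. In simulated data, a list of 30 genes shifted by 0.5 on the log2 scale was found in 10 of 10 data sets, and smaller lists and correlated genes were not simulated.

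Upper-quartile factors raised the median log2 fold change of all 3628 tested genes from -0.00234 to 0.0818, and library totals alone raised it to 0.0381, so list medians moved with it. Under upper-quartile factors the medians were 0.196 for denitrification, 0.164 for flagellum and chemotaxis, 0.136 for cationic peptide resistance, 0.133 for ribosomal proteins and -0.0377 for assimilatory nitrogen. Under library totals alone they were 0.0956 for cationic peptide resistance, 0.104 for ribosomal proteins, -0.0465 for assimilatory nitrogen and -0.0393 for amino acid biosynthesis.

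The libraries did not separate by group on their main axis of variation. The first principal component held 20.8% of the variance, and the groups' scores on it did not differ (exact permutation p = 0.357, n = 5 each). The difference reached an exact permutation p of 0.0159 without control 4 and without control 5, libraries that stood at opposite ends of that component. The second component held 18.9% of the variance, with a mean score of -7.95 ± 6.23 in DDDY and 7.95 ± 11.3 in control cultures (SD, n = 5 each; exact permutation p = 0.0317), which adjusted to 0.222 over 7 library measures. Here too, a single measure could not have passed after adjustment, given the smallest p that the relabellings allow. Total counts were 7948900 ± 2124800 in DDDY and 7240800 ± 1192000 in control libraries (SD, n = 5 each; exact permutation p = 0.508). The 10 genes most abundant over all libraries took 15.5% ± 1.16 of the counts in DDDY and 16.2% ± 0.611 in control libraries (SD, n = 5 each; exact permutation p = 0.333). All permutation tests were two-sided.

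No gene of type III secretion, the needle complex that injects toxins into host cells, had a read in any of the 10 libraries, over 32 measured members that include *exoS*, *exoT*, *exoY* and *pcrV*. At the depth of these libraries, a count of 0 allows up to 0.581 to 1.10 pairs per 1000000, for counting error only. In all, 1120 genes (20.1%) had no read in any library, and no fold change was computed for them.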

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

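The tests of DDDY 5 were chosen after its values were seen. In each group of 5 libraries, a value was noted when its gap to the nearest other library exceeded 0.71 of the group's range. Of 202 groups of values looked at, 13 held such a value, and chance gives about 1 in 20, or 10.1.

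Control 5 stood apart 6 times. The mean log2 CPM of tyrosine and phenylalanine catabolism genes was 7.484 there and 7.898 to 8.047 in the other control libraries. Within that list, *dhcA* was at 8.535 (others 9.384 to 9.721), *hmgA* at 9.961 (others 10.62 to 10.81) and *hpd* at 9.207 (others 9.948 to 10.23). The protease gene *lon* was at 7.324 (others 8.253 to 8.571), and *mpl* was higher than elsewhere at 6.732 (others 6.315 to 6.418).

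Control 4 stood apart 4 times, with higher log2 CPM of *fleQ* at 6.41 (others 6.049 to 6.059), *trpE* at 7.30 (others 6.96 to 7.047) and *pbpA* at 7.309 (others 7.014 to 7.045), and lower *glpR* at 5.995 (others 6.573 to 6.787). DDDY 1 stood apart for *pbpA* at 6.516 (others 6.786 to 6.891) and for PA1328 at 4.176 (others 3.283 to 3.464).

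The magnesium transporter gene *mgtA* was at a log2 CPM of 8.409 in DDDY 5 and at 3.50 to 4.021 in the other DDDY libraries, which is 340 CPM against 14.4 ± 2.31 CPM (SD, n = 4) and 15.5 ± 5.11 CPM in control libraries (SD, n = 5). In the same library *dnaK*, *groEL*, *hslU*, *hslV*, *clpB*, *htpG* and *ibpA*, chaperone or protease genes of the heat shock response, were 2.24 to 4.39 times lower than the mean of the other DDDY libraries, while the proteases *lon*, *clpX*, *ftsH* and *clpP* of the same list were at 129, 916, 1420 and 831 CPM against 175 ± 42.1, 1022 ± 111, 1526 ± 96.2 and 753 ± 43.1 CPM (SD, n = 4). A lower depth may leave such gaps by chance. With every library thinned to 2722782 pairs, the mean log2 CPM of the heat shock list in DDDY 5 was still -0.767 from that of the other DDDY libraries. Thinning hardly moves the expected values of genes this abundant, so it says little about depth. DDDY 1, with the fewest pairs (2722782), had a mean of 9.234, against 8.44 in DDDY 5. Without thinning, the mean of DDDY 5 lay -0.475 from the lowest control library, with a control SD of 0.169. The list's score did not separate the groups (exact permutation p = 0.294), and DDDY 5 lay below the other libraries of both. *mgtA*, at 340 CPM, also lay above the highest control library, at 23.4 CPM. Both values argue against a control culture under this label as the explanation of the pattern, since the control libraries did not show it. Whether the label is right cannot be decided from a library that lay outside both groups. A few abundant genes taking more of its counts could lower the other genes alike, but with library totals alone the median log2 difference of 2663 other genes from the other DDDY libraries was -0.0257 (quartiles -0.261 and 0.186), against a mean of -0.728 for the heat shock list. What stays open includes a difference in handling or growth stage. No biological explanation was tested.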

How the results depend on the processing

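Halved counts, an adjusted p below 0.10, leaving out control 5 with DDDY 5, unstandardized fry, camera with an estimated correlation and 1 library left out, and the DESeq2 refits were chosen after the data were seen. The edgeR count of 0 genes stayed at 0 under DESeq2 size factors, upper-quartile factors, library totals alone, the stricter filter, no robust estimation, halved counts, limma-voom and an adjusted p below 0.01. It was 71 with DESeq2, 2 with no filter and 2 at an adjusted p below 0.10 (PA1009 and *glpR* in both), and 4 without control 5 and DDDY 5 (PA0201 and PA2553 higher, *lon* and *hpaA* lower). Leaving out 1 library gave 0 to 21 genes (3 without DDDY 1, which were *glpR*, PA1328 and PA3043), and 312 genes without DDDY 4 to 572 without control 5 at an unadjusted p below 0.05, against 453 with all libraries. The DESeq2 count of 71 was 67 with halved counts, 61 without independent filtering, 98 without control 5 and DDDY 5, and 3 to 143 with 1 library left out. The list count of 0 became 1 without control 5 (0 to 1 with 1 library left out, and 0 each time with an estimated correlation), and the 1 list of fry's mixed test became 0 without standardization. The share of variance on the first principal component was 21.61 to 23.19% with 1 library left out, and its group difference passed without control 4 (21.69%) or control 5 (23.06%). The cause of these changes was not tested.

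Equal replicate numbers did not pair the libraries. Their deviations from the group means correlated across genes by -0.114, -0.12, 0.0278, 0.0772 and 0.126. Only DDDY 4 and DDDY 5 correlated best with the library of their own number in the other group, and no control library did. With the replicate block edgeR called 3 genes, 435 at an unadjusted p below 0.05 and 0 lists, DESeq2 67 genes of which 47 were among its 71, and the median of the aspartate list was -0.0015.

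Of 817 medians of the 43 tested lists under the alternatives, 130 changed sign, in 31 lists, and 1 list newly passed. The rest of this part covers the 12 lists described, chosen after the values were seen, of whose 228 medians 31 changed sign and 196 kept both sign and call. The peptidoglycan median of -0.0232 became 0.0633 under upper-quartile factors, 0.0157 under library totals, 0.00409 with no filter, 0.00868 with the stricter one, 0.00365 with limma-voom, 0.0214 with halved counts and 0.00567 without control 5 and DDDY 5. Amino acid biosynthesis became 0.00251 under upper-quartile factors, cationic peptide resistance -0.125 with no filter and -0.148 without control 5 and DDDY 5, envelope stress -0.0152 in the latter, and the aspartate list -0.00245 with limma-voom. With 1 library left out the medians ranged from -0.0362 to 0.0696 for aspartate, -0.0219 to 0.0536 for peptidoglycan, -0.109 to 0.117 for cationic peptide resistance, -0.0352 to 0.197 for ribosomal proteins, -0.00379 to 0.0429 for peptide uptake and -0.159 to 0.00245 for assimilatory nitrogen. Of 1805 values for 86 named genes, 5 changed sign and 55 newly passed the threshold. Some of these genes were named because DESeq2 or another alternative called them, so part of the 55 was set by that choice. Without control 5 and DDDY 5, *fahA* was at -0.0212 and *mgtA* at -0.17, and with 1 library left out *fahA* ranged from -0.0415 to 0.110 and *mgtA* from -0.11 to 2.605. The depth and spread of these libraries limit what could be seen for small changes. In simulated counts with 200 changed genes per data set, edgeR found 34% of 1.5-fold changes, and the share may be lower where fewer genes change.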

Other observations

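The tests of the 4-hydroxyphenylacetate genes were chosen after their values were seen, and the test of runs of unread genes after the type III secretion genes had been seen to be unread.

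Several gene lists differed more between libraries of 1 group than between the groups. Control 4 and control 5 stood at the extremes of several of them. The mean log2 CPM of ribosomal protein genes ran from 10.5 in control 4 to 11.4 in control 5, a 1.84-fold range, with a within-group SD of 0.289 and a group difference of 0.04. ATP synthase genes ran from 9.84 in control 4 to 10.7 in control 5, a 1.82-fold range, and aminoacyl-tRNA synthetase genes from 7.84 to 8.42 in the same libraries. Branched-chain amino acid and histidine catabolism genes ran the other way, from 6.72 in control 5 to 7.69 in control 4. Pyochelin siderophore genes ranged from 4.05 in DDDY 3 to 5.29 in DDDY 5.

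The genes without a read in any library were 20.1% of all genes. Their share differed between lists, and no test of enrichment was run. Most lists held no unread gene, and listed genes as a whole were unread less often than 20.1%. The share over all genes is therefore a rough yardstick for a list. The unread genes held all 32 type III secretion genes and 10 of 20 pyoverdine genes (among them *pvdD*, *pvdJ* and the receptor gene *fpvA*). They held 10 of 28 secreted virulence genes (among them *toxA*, *lasA*, *lecA* and *rhlC*). Those 10 include *exoS*, *exoT* and *exoY*, which also count as type III secretion genes. Nearer to the share over all genes were 13 of 50 type IV pilus and fimbrial genes (26%, among them the pilin gene *pilA*). The same held for 7 of 24 quorum sensing genes (29.2%, *pqsA*, *pqsE* and *rhlI* among them). Below that share were 5 of 35 lipopolysaccharide genes (14.3%, *wzx*, *wzy* and *wzz* among them). Of the *arn* genes, which modify lipid A with aminoarabinose, *arnA*, *arnB*, *arnC*, *arnD*, *arnE*, *arnF* and *arnT* had none.

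For these unread genes, transcription too weak for the depth is argued against as the main cause, since 1120 genes had 0 pairs and 88 had exactly 1 pair over all libraries, a ratio of 12.7, where a smooth tail was set to give less than 3. Genes that are missing or diverged in ATCC 9027 relative to the PAO1 gene set are a candidate explanation. Runs of 10 or more neighbouring unread genes held 287 genes (25.6% of the unread ones) in 19 runs, the longest of 36 genes from PA1690 to PA1725, against at most 0 genes in 1000 shuffled gene orders. The longest run holds 29 of the type III secretion genes, and the 18 other runs held 251 genes. Silent neighbouring genes of 1 operon would also form runs, and loss of a gene and divergence beyond what the aligner accepts cannot be separated without the genome of the strain.

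The 453 genes at an unadjusted p below 0.05 were more than most other divisions of the libraries gave. Of 100 splits into 5 and 5, drawn from 126 with the real one included, 5 gave at least 453 genes, the highest other 618 and the median of the others 129, so chance could not be excluded for this count. The 71 DESeq2 genes were reached by 4 of the 100 splits, with 177 as the highest other. That share lies just under 0.05 and 26 of the splits were not run, so chance is not firmly excluded. For the edgeR count of 0 genes and the list count of 0, with 42 genes and 18 lists as the highest others, the 100 of 100 splits that gave as many say nothing about chance, since no split can give fewer. The median of the other splits was 0 genes and 4 lists. Camera at the preset correlation thus often passed lists for other groupings, which also limits the ribosomal pass without control 5. The split of control 1, control 5, DDDY 2, DDDY 4 and DDDY 5 against the rest gave 177 DESeq2 genes and 18 lists, which may point to a structure of the samples that the labels do not name, although it was picked as the highest of the splits run. Exchanging control 4 with DDDY 2 gave 42 edgeR genes.

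A hypothesis from these values is that transcripts for 4-hydroxyphenylacetate breakdown, a route for aromatic compounds, may be lower as a unit in DDDY cultures. Besides *hpaA* at -0.93 and PA4122 at -1.10, all other genes from PA4121 to PA4128 were tested and had negative log2 fold changes, from -0.69 (*hpcC*) to -0.34 (*hpcB*). The mean log2 CPM of the 5 genes from PA4124 to PA4128 was 3.72 ± 0.19 in DDDY and 4.19 ± 0.39 in control cultures (SD, n = 5 each; exact two-sided permutation p = 0.0476). Their single values had been seen before this test and 2 of them, *hpcG* and *hpcD*, had an unadjusted p below 0.05 by edgeR, so it decides nothing on the hypothesis, and the lowest control library, at 3.79, lay below the highest DDDY library, at 4.01. The reductase gene *hpaC* did not share the direction, with a log2 fold change of 0.14 ± 0.43 (SE). The whole tyrosine and phenylalanine list did not pass camera (adjusted p = 0.825), so the wider form of the hypothesis stays open.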
